A study of Mus musculus with 32 samples.

How the data were processed

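The series held 32 Affymetrix Mouse Genome 430 2.0 arrays from 3 experiments. RNA was isolated with a column kit and amplified from its 3' end, per the labels' protocols. The values used here were log2 expression values that the authors deposited as a single matrix of 45101 probe sets, made with RMA per the submitters' processing notes. RMA corrects background, normalises arrays to a common distribution and summarises the probes of each probe set on the log2 scale. The base of the logarithm was not stated in the sources used here and was taken as log2. In the deposited matrix the median of each of the 45101 probe sets over the 6 arrays of the 230238 experiment and over the 8 arrays of the Ebf1-ER experiment was 0, within 1e-05, so the values had been centred per probe set within each experiment. In the tumour experiment 10846 probe sets had a median of 0 over its 18 arrays, which is 24.0% of them, and 6 to 11 of the 18 arrays lay above 0 for any probe set, so those values were centred on another constant. Array medians lay between -0.014 and 0.049. Centring leaves differences between arrays of an experiment as they were, but expression levels, signal over background and differences between experiments could not be read from these values. The number of arrays limits the precision.

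Groups were taken from the sample labels. The first experiment compared 3 samples of the mouse pre-B cell line 230238 transduced with Ebf1-Engrailed, a fusion of the B-cell transcription factor Ebf1 to the Engrailed repressor domain, with 3 transduced with the empty vector, and used 500000 sorted cells per sample. The second followed Ebf1-deficient fetal liver cells carrying Ebf1-ER, a form of Ebf1 that 4-hydroxytamoxifen activates, at 0, 6, 12 and 24 h, with 2 arrays per time. The third compared lymph nodes of 8 tumour-bearing mice, 2 arrays each, with 2 arrays of wild-type pro-B cells. The titles of the lymph nodes and of the wild-type samples carry numbers, read here as 1 mouse each, though the labels do not explain them. Whether the replicates of the other groups came from separate cultures or animals is not stated, so p-values measure the spread between these samples, which may be technical. No 2 arrays held identical values. The smallest median absolute difference between any pair within an experiment was 0.0911 on the log2 scale.

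Probe sets were named from the platform annotation, with symbols updated through the gene table supplied for the mouse: 34945 probe sets had 1 gene symbol, 932 had several and 9224 had none. Of the 34945, 34741 were matched to the gene table supplied, and 204 kept the array's name. Probe sets with several genes or none were not used, which left 18193 genes, 9010 of them with more than 1 probe set. Before the data were examined, the plan named a filter on low values, the probe set with the highest mean per gene and an intensity trend in the variance model. All of these need expression levels, so they could not be applied to centred values. The alternatives fixed beside them took their place: no filter, the probe set with the largest variance over the arrays of the experiment, and no trend. That change was made after the scale of the values was seen. Choosing the most variable probe set favours large differences, so the mean of all probe sets of a gene was run beside it.

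Differences were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with version 1.17.8 of the data.table package for reading tables, a separate fit per experiment and 1 estimate of the spread for its groups. Adjusted p-values are two-sided and use the Benjamini-Hochberg method over all 18193 genes, and a gene was called at an adjusted p under 0.05. The 2 arrays of each lymph node were averaged before the comparison with wild-type cells. Differences between lymph nodes were tested over their 16 arrays with limma's moderated F test against the spread between the arrays of a lymph node, which may be technical. Errors beside log2 changes are limma's standard errors.

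For each comparison 26 gene lists, fixed before the data were examined, were tested with limma's camera at a preset correlation of 0.01 between genes, with adjustment over the lists. Beside each list stand its members past the threshold over all genes and those past it when adjusted over the list alone. Camera with a correlation estimated from the residuals and fry were run as alternatives. Camera compares a list with all other genes, and fry asks whether the genes of a list move one way. Genes called in one experiment were also tested as lists in the others, Ebf1 itself left out, with adjustment over 8 tests. Members of the 26 lists without a probe set assigned to a single gene were not analysed here.

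The genes named in the text followed a rule fixed in advance. It takes Ebf1, Pax5, Myc, Rad51ap1, Cd79a, Igll1, Foxo1 and Il7r always, then the 6 largest increases and the 6 largest decreases among called genes whose groups did not overlap, and then up to 3 called members of each list with the largest change. From the test between lymph nodes it takes the 10 called genes with the largest variance. Other genes of the fixed rule were not analysed here. Immunoglobulin and T-cell receptor segments, sex-linked genes and unnamed transcripts were left out of that choice and counted as classes.

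After the group means were subtracted, Ebf1-Engrailed and empty-vector samples with the same number from 1 to 3 correlated at 0.256, 0.387 and 0.481 over genes. Ebf1-Engrailed sample 1 correlated more with empty-vector sample 2, at 0.344, than with the sample of its own number. Both samples numbered 3 stood apart from the others. The data thus set number 3 apart but do not settle whether numbers 1 and 2 are pairs. The planned fit has no block, and the replicate block was run as an alternative.

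The gene tests of the comparisons below were run on simulated data drawn independently per gene with the real residual spread of all 18193 genes. In the group comparisons 200 genes were changed by a log2 value of 0.5, 1 or 2, and a further list of 30 genes was shifted by 0.5. Correlation between genes, the choice of probe set, 6 h and 12 h against 0 h, fry and lists from other experiments were not simulated. The share of changed genes was also smaller than the share called in the data. With a change of 1 on the log2 scale, 68.9% of the changed genes were recovered for Ebf1-Engrailed against the empty vector, 69.1% for 24 h against 0 h, 76.6% for 24 h against 6 h and 63.8% for tumours against wild-type cells. With a change of 0.5 the shares were 17.2%, 25.3%, 19.7% and 24.6%, and with a change of 2 they were 92.0%, 93.1%, 96.8% and 88.2%. Between 4 and 13 of the 17963 unchanged genes were called per comparison. In the simulated test between lymph nodes 200 of 200 genes with a standard deviation of 1 between lymph nodes were recovered and 11 of 17993 unchanged genes were called.

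The alternatives tried were the mean of all probe sets, array centring, robust eBayes, stricter thresholds, the replicate block, 1 fit over all groups, a random block or single duplicates for lymph nodes, array weights, and leaving out each sample in turn. After the data were seen, 6 kinds were added: a variance filter, the comparison without the samples numbered 3, crossed numbers at 24 h, the 24 h to 6 h contrast without the 0 h arrays, a term for Xist-high samples, and gene lists taken from or tested in 24 h against 6 h. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.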

Results

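Transcript abundance was measured on 32 arrays of mouse B-lineage cells in 3 experiments built around the transcription factor Ebf1, which early B-cell development requires. The 230238 pre-B cell line carried Ebf1-Engrailed on 3 arrays and an empty vector on 3. Ebf1-deficient fetal liver progenitors carrying the tamoxifen-activated Ebf1-ER were measured at 0, 6, 12 and 24 h on 2 arrays each. Lymph nodes from 8 mice of about 30 weeks with heterozygous loss of Ebf1 and Pax5 were measured on 2 arrays each beside 2 arrays of wild-type pro-B cells. All values are log2 RMA values centred per probe set within an experiment, so the results below are differences between groups of an experiment for 18193 genes, with limma's standard error, and no absolute levels are given.

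The first comparison asked which transcripts change when a repressive form of Ebf1 is expressed in pre-B cells. Ebf1 itself was 3.41-fold lower with Ebf1-Engrailed (log2 change -1.77 ± 0.25 SE, n = 3 and 3, adjusted p = 0.0049). Of its 5 probe sets 4 fell, 2.83-fold to 3.41-fold. The other did not pass the threshold (log2 change -0.37). The arrays do not separate the cell's own transcript from that of the vector. Components of the pre-B receptor fell. Igll1, a surrogate light chain gene, was 17.6-fold lower (log2 change -4.14 ± 0.31) and Vpreb3 8.21-fold lower. Only 1 of 2 probe sets of Igll1 passed, with none called in the opposite direction. Cd79b, a signalling chain of the receptor, was 4.40-fold lower. Among the largest increases were Fcer1g, an Fc receptor chain, at 93.6-fold (log2 change 6.55 ± 0.48), the chemokine Ccl3 at 85.0-fold and the growth factor Csf2 at 50.0-fold.

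Among early B-lineage genes 14 of 23 measured members fell and 9 did not pass the test (adjusted over the list alone, 18 fell). The list test gave an adjusted p of 1.9e-10, and adjusted p = 0.13 with an estimated correlation. Vpreb1, the partner of Igll1, changed by -2.29 ± 0.44 and Foxo1, a transcription factor of B-cell specification, by -0.82 ± 0.16. Cd79a changed by -0.97 ± 0.13, whereas Pax5 (-0.42 ± 0.18) and Il7r, the interleukin-7 receptor (0.46 ± 0.33), did not pass. In pre-B receptor signalling 8 of 17 members fell and 1 rose (9 and 1 adjusted over the list alone, adjusted p = 3.7e-05, and adjusted p = 0.13 with an estimated correlation).

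Genes of cell division fell together. In DNA replication 30 of 39 members fell and none rose (35 adjusted over the list alone, adjusted p = 3.3e-22). Tyms, which makes thymidylate, stood at -1.66 ± 0.26 and the helicase subunit Mcm4 at -1.64 ± 0.12. In mitosis 26 of 32 fell (31 adjusted over the list alone, adjusted p = 1.1e-19). The spindle motor Kif11 stood at -1.66 ± 0.22 and the kinase Aurkb at -1.42 ± 0.21. In homologous recombination and Fanconi repair 18 of 37 fell (24 fell and 2 rose adjusted over the list alone, adjusted p = 3e-09). Rad54b stood at -1.76 ± 0.25, Brca1 at -1.47 ± 0.23 and Rad51ap1, a partner of the strand-exchange protein, at -1.35 ± 0.16. In the DNA damage checkpoint 9 of 25 fell (13 adjusted over the list alone, adjusted p = 3.8e-07), with the kinase Chek1 at -1.49 ± 0.13. With an estimated correlation all of these lists had an adjusted p = 0.13. In base excision, mismatch and nucleotide excision repair 9 of 35 fell and 3 rose (12 and 4 adjusted over the list alone, adjusted p = 0.0087, and adjusted p = 0.38 with an estimated correlation). The glycosylase Neil1 stood at -1.46 ± 0.28.

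Glycolysis genes rose. Of 18 members 12 were higher and none lower (13 adjusted over the list alone, adjusted p = 2.5e-09, and adjusted p = 0.064 with an estimated correlation). The glucose transporters Slc2a3 and Slc2a1 were 5.43-fold and 4.90-fold higher and pyruvate kinase, Pkm, 3.99-fold. Of 29 interferon response genes 11 rose (18 adjusted over the list alone, adjusted p = 1.8e-08, and adjusted p = 0.49 with an estimated correlation). The call was lost with fry (adjusted p = 0.145). Ifit1, an antiviral effector, stood at 5.08 ± 1.07 on the log2 scale. The mean of the list lay 2.68 and 2.62 above the empty vector for replicate numbers 1 and 2 but 0.689 above it for number 3. Ifit1, Rtp4 and Usp18 lost their calls in leave-one-out fits. Myeloid markers had 6 of 33 members higher and 1 lower (6 and 1 adjusted over the list alone, adjusted p = 0.012, and adjusted p = 0.13 with an estimated correlation). The call was lost in 1 fit over all groups of the series (adjusted p = 0.168). Among the 6 were Fcgr3 at 2.69 ± 0.38 and the lysosomal Cd68 at 2.16 ± 0.39. NK and innate lymphoid markers had 4 of 21 higher (4 adjusted over the list alone, adjusted p = 0.048, and adjusted p = 0.47 with an estimated correlation). Id2, an inhibitor of E-protein transcription factors, stood at 2.83 ± 0.27. That list did not pass with the replicate number as a block (adjusted p = 0.0503), without Ebf1-Engrailed sample 2 (adjusted p = 0.0917) or without empty-vector sample 3 (adjusted p = 0.127), nor without both samples numbered 3 (0.0615) or in 1 fit over all groups (0.411).

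The other 15 lists did not pass. Single members still changed, among them Lat, an adaptor of T-cell receptor signalling, at 3.57 ± 0.22, the antigen presentation gene H2-Aa at 2.21 ± 0.24 and the adhesion receptor Cd44 at 4.73 ± 0.32. So did the transcription factors Erg at -2.99 ± 0.29 and Irf4 at -2.62 ± 0.30, the cyclin Ccnd3 at -1.72 ± 0.22 and the polyamine enzyme Odc1 at 2.29 ± 0.36. Of the probe sets, 2 of 4 of Cd44, 1 of 2 of Erg and 1 of 3 of Ccnd3 passed, with none called in the opposite direction. Myc did not pass (-0.59 ± 0.22), and its target and ribosome biogenesis list had 1 of 33 members higher and an adjusted p of 0.057. The remaining large changes were increases of Ier3, Mmp12 and Tnfrsf11b by 6.55, 6.22 and 6.05 and decreases of Gng4 (-3.98), Fetub (-3.61), Mfsd4a (-3.34), Mreg (-3.19) and Cabp4 (-3.16). In all, 2474 genes were called, 1442 higher and 1032 lower. The groups did not overlap for 5826 of the 18193 genes, where chance gives 10%. The count was 4772 without the samples numbered 3. It was 1134 without Ebf1-Engrailed sample 1, 1140 without sample 2, 1592 without empty-vector sample 1 and 1331 without sample 2. Of 81 called genes that the fixed rule names, 58 kept their call in every leave-one-out fit. Vpreb1, Foxo1, Neil1 and Cd68 were among those that did not.

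**Figure D1:**
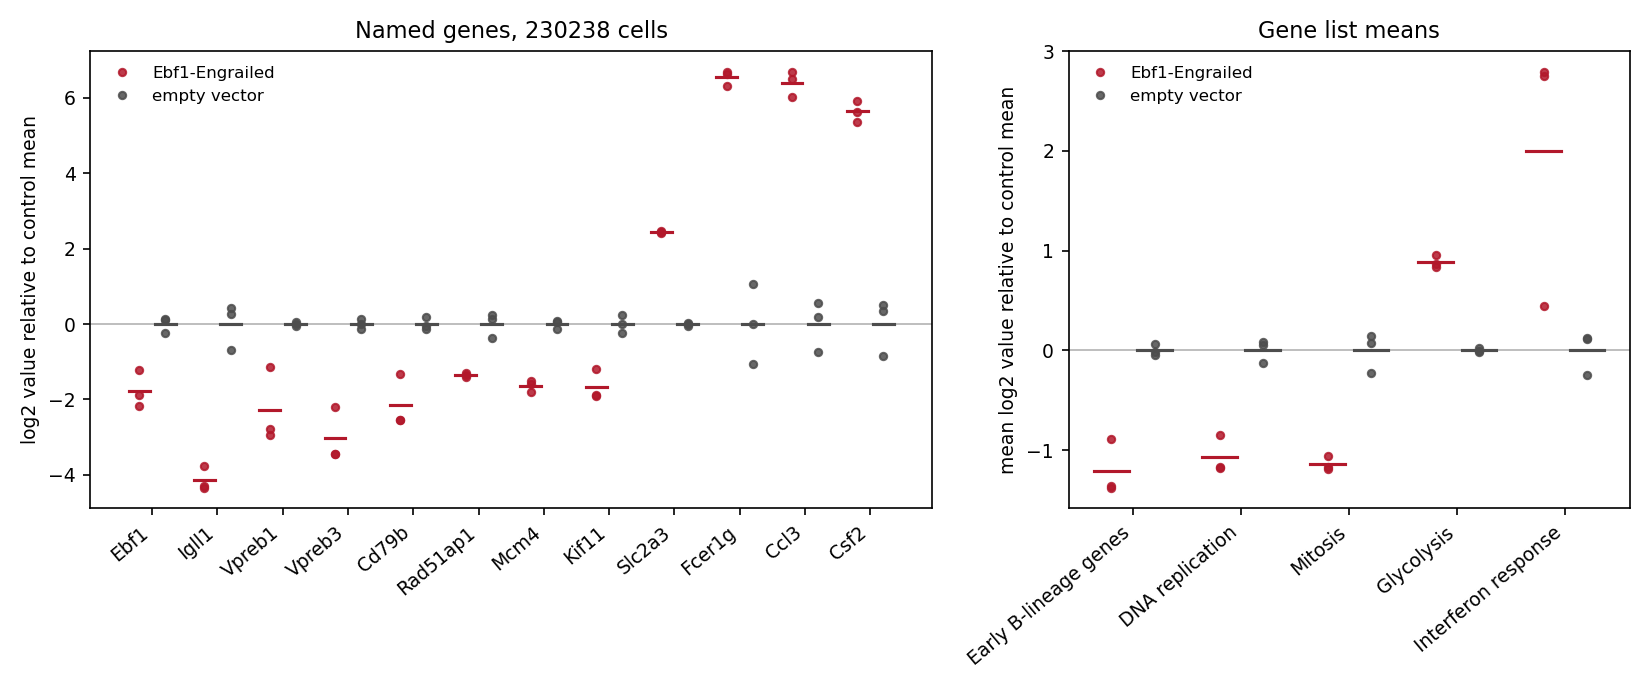
Values of named genes (left) and means of gene lists (right) in 230238 cells with Ebf1-Engrailed or the empty vector, as log2 values relative to the empty-vector mean, with points for the 3 arrays and bars for group means. Igll1 lies 4.14 below and Fcer1g 6.55 above the empty vector, and the interferon list is lower in 1 Ebf1-Engrailed array than in the others.

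The second comparison asked how Ebf1-deficient progenitors respond once Ebf1-ER is activated. At 24 h Igll1 was 12.0-fold higher than at 0 h (log2 change 3.59 ± 0.09 SE, n = 2 and 2, adjusted p = 1.4e-06), Cd24a, a surface marker of early B cells, 4.02-fold higher and Vpreb1 3.92-fold higher. Ebf1 transcript was lower (-0.77 ± 0.08) on 4 of 5 probe sets, and the arrays do not separate the vector's Ebf1 from the disrupted gene. Immediate-early genes fell far below their 0 h values: Fos was 128-fold lower, Egr3 60.6-fold, Egr1 41.5-fold and Egr2 34.9-fold. Ccl3 stood at -5.38 and the GTPase Gbp8 at -5.04. Among the largest increases were Tubb3, a tubulin, at 27.0-fold, Ccn3 at 19.4-fold, Bcat1, an enzyme of branched amino acid breakdown, at 14.7-fold, Nefh at 12.7-fold and P2rx3 at 11.8-fold. The 0 h arrays stood apart from all later ones on a first principal component that held 65.7% of the variance. That separation moves with every gene group compared with 0 h. The labels give 4-hydroxytamoxifen for the later times only, so its own effect, time in culture and Ebf1-ER cannot be told apart there.

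All 33 Myc target and ribosome biogenesis genes rose at 24 h (33 adjusted over the list alone, adjusted p = 3.7e-20). Spermidine synthase, Srm, stood at 2.85 ± 0.11, while Myc itself fell by 0.93. All 39 DNA replication genes rose (39 adjusted over the list alone, adjusted p = 3e-21), among them the licensing factors Orc1 at 2.68 ± 0.16 and Cdc6 at 2.59 ± 0.09. In homologous recombination and Fanconi repair 30 of 37 rose and 2 fell (30 and 3 adjusted over the list alone, adjusted p = 6.8e-11). The nucleases Exo1 and Dna2 stood at 2.67 ± 0.09 and 2.22 ± 0.11 and Rad51ap1 at 1.98 ± 0.11. In the checkpoint list 19 of 25 rose (22 adjusted over the list alone, adjusted p = 4.6e-08), with Chek1 at 2.83 ± 0.16. In mitosis 30 of 32 rose and 1 fell (30 and 1 adjusted over the list alone, adjusted p = 1.1e-12), with Ncapg, a condensin subunit, at 2.01 ± 0.12. These 5 lists passed with an estimated correlation too. Early B-lineage genes had 10 of 23 members higher and 2 lower (10 and 4 adjusted over the list alone, adjusted p = 0.025, and adjusted p = 0.34 with an estimated correlation). This call was lost with the mean of all probe sets (adjusted p = 0.0639), with a variance filter (0.0960) and in 1 fit over all groups (0.165). Foxo1 changed by 0.70 ± 0.10, Cd79a by 0.36 ± 0.15 and Pax5 by 0.30 ± 0.13, the last 2 not past the threshold. Only 1 of 4 probe sets of Foxo1 and 1 of 2 of Igll1 passed, with none called in the opposite direction.

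Glycolysis genes had 12 of 18 members higher and 4 lower (12 and 4 adjusted over the list alone, adjusted p = 0.011, and adjusted p = 0.28 with an estimated correlation). Hexokinase, Hk2, stood at 1.69 ± 0.09. In excision and mismatch repair 17 of 35 rose and 6 fell (20 and 6 adjusted over the list alone, adjusted p = 0.014, and adjusted p = 0.082 with an estimated correlation). The call was lost with a variance filter (adjusted p = 0.195). The uracil glycosylase Ung stood at 2.25 ± 0.10. The V(D)J recombination list did not pass (adjusted p = 0.70), although Dntt, which adds untemplated nucleotides at V(D)J joints, fell by 3.31.

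Most other lists fell at 24 h. Of 24 immediate-early and stress genes 21 were lower (21 adjusted over the list alone, adjusted p = 1.3e-15). Of 29 interferon response genes 25 were lower (26 adjusted over the list alone, adjusted p = 1.4e-13), among them Usp18 at -3.10 ± 0.14. Of 21 NK and innate lymphoid markers 15 were lower (16 adjusted over the list alone, adjusted p = 2.3e-08), among them the receptor Klrd1 at -3.20 ± 0.10. Mature B-cell markers had 10 of 22 lower (10 adjusted over the list alone, adjusted p = 0.0008), with Ltb at -2.20 ± 0.09. These 4 lists passed with an estimated correlation too. In IL-7 receptor and STAT5 signalling 13 of 19 fell and 3 rose (14 and 3 adjusted over the list alone, adjusted p = 2.5e-05, and adjusted p = 0.082 with an estimated correlation). Il7r stood at -1.24 ± 0.16 and Socs3 at -2.44 ± 0.14. Bcl2, an inhibitor of apoptosis, and Ccnd3 stood at -2.68 and -2.60 on the probe sets used. However, 2 of 5 probe sets of Bcl2 and 1 of 3 of Ccnd3 changed past the threshold in the opposite direction. Of 27 p53 targets 13 fell and 4 rose (13 and 4 adjusted over the list alone, adjusted p = 0.0044, and adjusted p = 0.28 with an estimated correlation). Btg2, an inhibitor of proliferation, stood at -3.07 ± 0.09. T-cell markers had 11 of 24 lower and 1 higher (adjusted p = 0.0052, and adjusted p = 0.28 with an estimated correlation). Stem and progenitor markers had 10 of 20 lower and 3 higher (adjusted p = 0.0047, and adjusted p = 0.16 with an estimated correlation). Stromal markers had 9 of 24 lower (adjusted p = 0.0024, and adjusted p = 0.32 with an estimated correlation). Adjusted over the list alone these counts were 11 and 1, 10 and 3, and 9. The T-cell call was lost in 1 fit over all groups (adjusted p = 0.0939). Trat1, an adaptor of T cells, changed by -2.80 ± 0.17, Mn1 by -1.71 ± 0.10 and Thbs1, a matrix glycoprotein, by -3.27 ± 0.31. Surface genes of pro-B and pre-B cells had 12 of 20 lower and 4 higher (13 and 5 adjusted over the list alone, adjusted p = 0.0018, and adjusted p = 0.056 with an estimated correlation). The integrin Itga4 stood at -3.50 ± 0.10.

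The BCL2 family also passed (7 of 14 lower and 2 higher, adjusted p = 0.0056, and adjusted p = 0.082 with an estimated correlation). So did genes altered in B-cell leukaemia (13 of 26 lower and 5 higher, adjusted p = 0.0054, and adjusted p = 0.28 with an estimated correlation). Myeloid markers had 8 of 33 lower and 4 higher (adjusted p = 0.021, and adjusted p = 0.28 with an estimated correlation). Adjusted over the list alone the counts were 8 lower and 3 higher, 14 and 6, and 8 and 4. The myeloid call was lost without 0 h array 1 (adjusted p = 0.0819). Btg1 changed by -2.28 ± 0.21 and the integrin Itgam by -2.34 ± 0.23. Plasma-cell, pre-B receptor, histone and erythroid lists did not pass, with single changes of Mzb1 at 1.41 ± 0.09, the kinase Fyn at -1.39 ± 0.09, H2aw at -2.48 ± 0.18 and Car2 at 1.30 ± 0.10. In all, 7060 genes were called, 3823 higher and 3237 lower. Of these, 2074 had a log2 change of at least 1. Among 2945 genes with at least 2 called probe sets, 304 had called probe sets in opposite directions.

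The earlier times were compared with 0 h in the same way. At 6 h, 6381 genes differed from 0 h, 3390 higher and 2991 lower, and at 12 h 7242, of which 3618 were higher and 3624 lower. Myc target and ribosome biogenesis genes had already risen at 6 h (33 of 33, 33 adjusted over the list alone, adjusted p = 3.3e-23). Immediate-early and stress genes had fallen (21 of 24 lower and 1 higher, 21 and 1 adjusted over the list alone, adjusted p = 1.3e-16). Mitosis genes were lower at 6 h (21 of 32, 21 adjusted over the list alone, adjusted p = 9e-09). They were higher at 12 h (22 of 32, with 3 lower, 23 and 3 adjusted over the list alone, adjusted p = 5.5e-05). All of these calls held with an estimated correlation, but that of mitosis at 12 h was lost in 1 fit over all groups (adjusted p = 0.0691). Aurkb changed by -0.07 ± 0.11 at 6 h, not past the threshold, 1.38 ± 0.11 at 12 h and 1.69 ± 0.11 at 24 h. Igll1 changed by 0.74 ± 0.09, 1.78 ± 0.09 and 3.59 ± 0.09 at 6, 12 and 24 h, and Myc by 0.23 ± 0.10, 0.23 ± 0.10 and -0.93 ± 0.10, of which the last value passed.

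A direct test of 24 h against 6 h leaves out the 0 h means. All 32 mitosis genes were higher at 24 h (32 adjusted over the list alone, adjusted p = 3.4e-47), with Bub1, a spindle checkpoint kinase, at 2.11 ± 0.12. DNA replication had 29 of 39 higher (35 adjusted over the list alone, adjusted p = 7.5e-24). Homologous recombination had 22 of 37 higher and 1 lower (24 and 4 adjusted over the list alone, adjusted p = 1.9e-12). These 3 lists passed with an estimated correlation. Early B-lineage genes had 9 of 23 higher and none lower (13 adjusted over the list alone, adjusted p = 4.3e-09, and adjusted p = 0.10 with an estimated correlation). Among them were Igll1 at 2.85 ± 0.09, Cd24a at 2.27 ± 0.11, Vpreb1 at 1.08 ± 0.12 and Foxo1 at 0.98 ± 0.10. Myc was lower at -1.16 ± 0.10. Of its 33 target and ribosome biogenesis genes 8 were lower and 2 higher (13 and 2 adjusted over the list alone, adjusted p = 0.00082, and adjusted p = 0.10 with an estimated correlation). In 1 fit over all groups that list had an adjusted p of 0.0510. Between these times 1693 genes differed, 895 higher and 798 lower at 24 h. The count was 681 and 746 without 6 h array 1 or 2 and 617 and 649 without 24 h array 1 or 2. It was 2017 without both 0 h arrays.

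**Figure D2:**
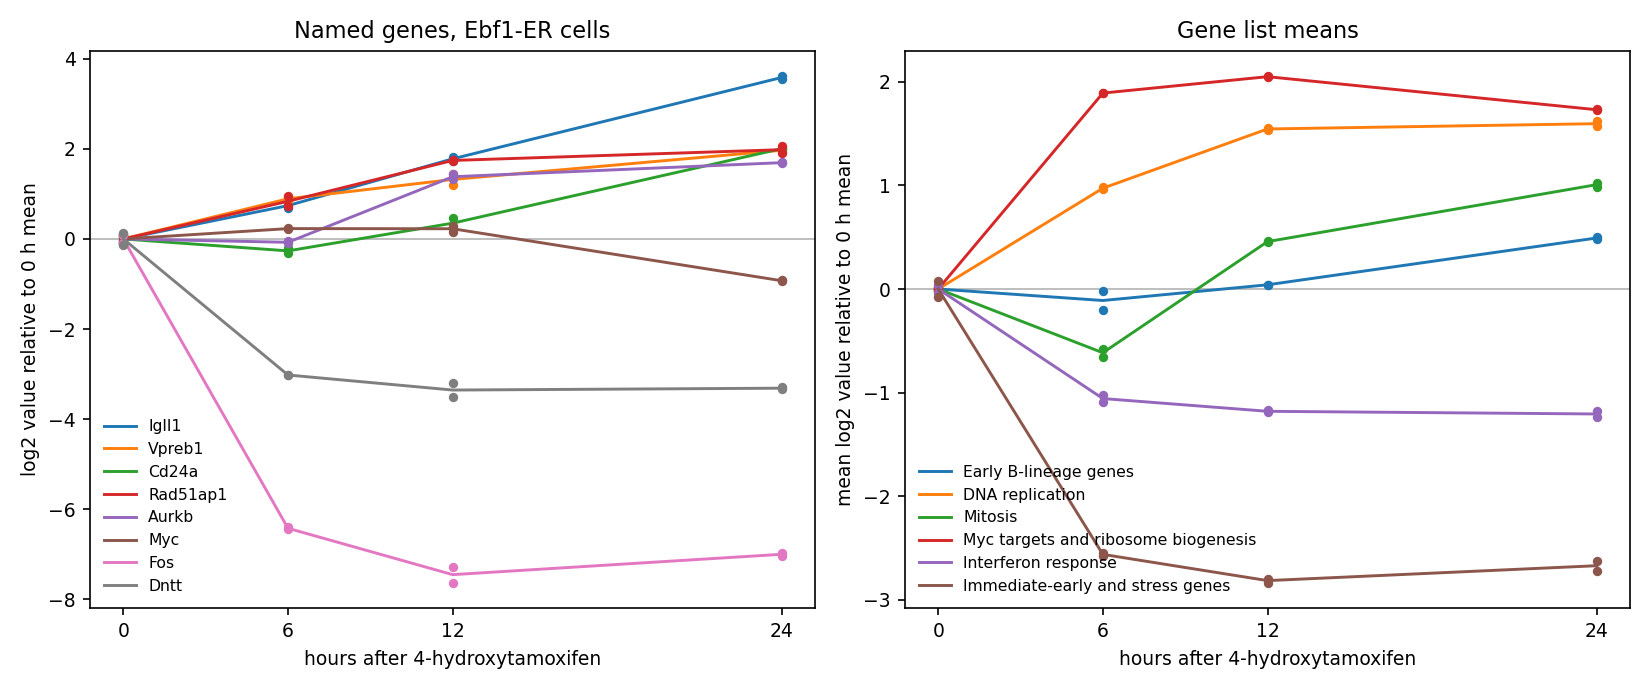
Log2 values of named genes (left) and means of gene lists (right) relative to the 0 h mean, against hours of 4-hydroxytamoxifen in Ebf1-ER cells, with points for the 2 arrays per time and lines through the means. Fos is 128-fold lower at 24 h and already low at 6 h, and Igll1 rises to 3.59.

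Genes that changed over time in the Ebf1-ER cells were compared with those that changed with Ebf1-Engrailed. The 2 experiments share no array. Of 3823 genes higher at 24 h than at 0 h, 540 were lower and 208 higher with Ebf1-Engrailed (adjusted p = 9.5e-05, and adjusted p = 0.35 with an estimated correlation). Independent lists would share 217 and 303. This call was lost with fry (adjusted p = 0.0964). Of 3236 genes lower at 24 h, 558 were higher and 166 lower with Ebf1-Engrailed (adjusted p = 0.0098, and adjusted p = 0.25 with an estimated correlation, expected 256 and 183). This call was lost without empty-vector array 2 (adjusted p = 0.0644) and without Ebf1-Engrailed array 3 (adjusted p = 0.0528). Read the other way, genes higher with Ebf1-Engrailed moved down at 24 h (adjusted p = 3.6e-07, and adjusted p = 0.22 with an estimated correlation). Genes lower with it moved up (adjusted p = 5.3e-08, and adjusted p = 0.067 with an estimated correlation), a call lost with lists of the 100 largest changes (adjusted p = 0.163). Lists from 24 h against 6 h were a test added after the data were seen. Of these, 315 of the 895 genes higher at 24 h were lower with Ebf1-Engrailed and 58 higher (adjusted p = 4.9e-13, and adjusted p = 0.043 with an estimated correlation). Independent lists would share 50.7 and 70.9. Of the 798 genes lower at 24 h than at 6 h, 135 were higher and 44 lower (adjusted p = 0.0075, and adjusted p = 0.37 with an estimated correlation). Igll1, Vpreb1, Rad51ap1, Chek1 and Foxo1 were among the genes lower with Ebf1-Engrailed and higher at 24 h than at 0 h.

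The third comparison set tumour-bearing lymph nodes against wild-type pro-B cells. The mice carry a single intact copy each of Ebf1 and Pax5. Of 5 Ebf1 probe sets 4 were 1.65-fold to 2.02-fold lower in the tumours. The other, which had the largest variance and so stands for the gene here, was 22.4-fold higher (log2 change 4.48 ± 0.18 SE, n = 8 lymph nodes and 2 arrays, adjusted p = 7.1e-08). With the mean of all probe sets Ebf1 did not pass. Of 2 Pax5 probe sets 1 was 1.70-fold lower and the other did not pass (0.40 ± 0.26). Where these probe sets lie relative to the disrupted parts of the genes was not analysed here. Granulocyte transcripts were far lower in the tumours: Lcn2, a granule protein that binds siderophores, stood at -9.45 ± 0.72 on the log2 scale, Chil3 at -9.13 ± 1.02 and Ngp at -8.54 ± 0.79. Ifitm6 stood at -8.52 ± 0.79, Camp at -8.08 ± 0.54 and Ltf, lactoferrin, at -8.06 ± 0.53. Among the largest increases were the cytokine Tnfsf11 at 27.7-fold, Sema6d at 26.2-fold, the cadherin Cdh17 at 20.2-fold, the adaptor Grb10 at 18.6-fold and the tumour suppressor Cdkn2a at 17.9-fold (4.16 ± 1.08). Adjusted over all probe sets, only 1 of 4 probe sets of Sema6d and 1 of 3 of Grb10 passed, and the single one of Cdh17 did not. None was called in the opposite direction.

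Of 33 Myc target and ribosome biogenesis genes 30 were higher in the tumours and none lower (31 adjusted over the list alone, adjusted p = 4.8e-15, and adjusted p = 0.46 with an estimated correlation). The RNA polymerase I subunit Polr1b stood at 2.02 ± 0.27 and Wdr12 at 1.71 ± 0.28. Myc itself was 3.21-fold higher (1.68 ± 0.46). Base excision and mismatch repair genes had 9 of 35 higher and 2 lower (11 and 3 adjusted over the list alone, adjusted p = 0.015, and adjusted p = 0.69 with an estimated correlation). The endonuclease Apex1 stood at 1.67 ± 0.18. Homologous recombination genes had 7 of 37 higher and 1 lower (7 and 2 adjusted over the list alone, adjusted p = 0.010, and adjusted p = 0.96 with an estimated correlation). Nbn stood at 0.94 ± 0.26, while Rad51ap1 did not differ past the threshold (-0.04 ± 0.28). DNA replication genes had 7 of 39 higher (6 adjusted over the list alone, adjusted p = 0.0043, and adjusted p = 0.96 with an estimated correlation). Cdc6 stood at 0.87 ± 0.26. Mitosis genes had 1 of 32 lower, Smc4 (-0.73 ± 0.20), and none when adjusted over the list alone. The list passed as lower (adjusted p = 0.028, and adjusted p = 0.97 with an estimated correlation). Early B-lineage genes had 4 of 23 lower (3 adjusted over the list alone, adjusted p = 0.028, and adjusted p = 0.82 with an estimated correlation). Cd72 stood at -1.60 ± 0.42 and Tcf3, an E-protein, at -1.56 ± 0.37. Igll1 (-0.72 ± 0.32), Cd79a (0.79 ± 0.34), Foxo1 (-0.90 ± 0.41) and Il7r (1.00 ± 0.38) did not pass. Immediate-early and stress genes had 6 of 24 lower (7 adjusted over the list alone, adjusted p = 0.0033, and adjusted p = 0.82 with an estimated correlation). Ier3 stood at -3.07 ± 0.59.

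Lists of markers of myeloid, erythroid, stem and stromal cells were lower in the tumours than in the wild-type pro-B samples. Of 33 myeloid markers 27 were lower (29 lower and 1 higher adjusted over the list alone, median log2 change -3.71, adjusted p = 7.5e-24). Erythroid and megakaryocyte markers had 11 of 16 lower (12 adjusted over the list alone, adjusted p = 9.2e-10), with the red cell anion exchanger Slc4a1 at -5.37 ± 0.32. Stem and progenitor markers had 6 of 20 lower (6 adjusted over the list alone, adjusted p = 0.00084), with Hoxa9 at -3.05 ± 0.08, Cd34 at -2.84 ± 0.17 and Meis1 at -2.44 ± 0.08. These 3 lists passed with an estimated correlation. Stromal markers had 9 of 24 lower (9 adjusted over the list alone, adjusted p = 6.7e-05, and adjusted p = 0.13 with an estimated correlation). Thbs1 stood at -3.63 ± 0.30 and smooth muscle actin, Acta2, at -2.09 ± 0.11. NK and innate lymphoid markers did not pass (2 of 21 lower, adjusted p = 0.47), and their mean lay 1.99 above wild-type cells in lymph node 279. T-cell markers did not pass either (1 of 24 higher, adjusted p = 0.24). The mean of that list lay 2.56 above wild-type cells in lymph node 279, 1.24 in lymph node 383 and 0.92 in lymph node 381.

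The other 13 lists did not pass. Single changes in the lists that did not pass included Socs2, a feedback inhibitor of cytokine signalling, at 2.64 ± 0.28, Itgb1 at 1.30 ± 0.22, Cd9, a tetraspanin, at -3.97 ± 0.68, and Gadd45a at -2.75 ± 0.48. Others were Rsad2 at -2.54 ± 0.50, Cdc25b at -2.06 ± 0.59, Pmaip1 at 1.98 ± 0.48 and Nfil3 at -1.93 ± 0.44. The recombinase gene Rag2 stood at -1.76 ± 0.44, H1f2 at -1.87 ± 0.48 and Pik3ap1 at -1.80 ± 0.38. Pfkl stood at 1.18 ± 0.25, with 1 of 3 probe sets changed in the opposite direction. Further changes were Ccr7 at 1.05 ± 0.24, Ctla4 at 2.16 ± 0.60 and Edem1 at -0.59 ± 0.17. In all, 3619 genes were called, 2047 higher and 1572 lower. The call count was 1716 without wild-type array 1 and 1117 without array 2. Of 73 called genes that the fixed rule names 22 kept their call in every leave-one-out fit. Those 22 include the granulocyte, erythroid and stem cell genes named above, Polr1b, Wdr12, Apex1, Socs2, Itgb1 and Tnfsf11, but not Myc, Cdkn2a, Sema6d, Cdh17 or Grb10. Both wild-type arrays and 2 of 8 lymph nodes were Xist-low. In those samples the Y-linked Eif2s3y lay 6.80 to 7.64 above its lowest value on the log2 scale. It lay at most 0.22 above it in the Xist-high lymph nodes. Kdm5d and Uty, also Y-linked, split the samples in the same way. By these transcripts the wild-type arrays and lymph nodes 279 and 292 were male and the other 6 lymph nodes female. With a term for Xist-high samples 1704 genes were called. As both wild-type arrays are Xist-low, the tumour difference in that fit is that of the Xist-low lymph nodes 279 and 292 alone. Calls lost there thus cannot be assigned to sex rather than to those 2 lymph nodes or their small number. Of the genes that the fixed rule names 39 lost their call in that fit, among them Myc, Cdh17, Grb10, Rag2, Pmaip1, Nfil3 and Ctla4, but none of the 22. The homologous recombination and DNA replication lists were no longer higher in that fit (adjusted p = 0.979 and 0.725, both in the opposite direction). The early B-lineage and the excision and mismatch repair lists lost their calls in it (adjusted p = 0.413 and 0.192). With a variance filter the homologous recombination, excision and mismatch repair and DNA replication lists did not pass (adjusted p = 0.122, 0.155 and 0.0579). With fry the early B-lineage (0.170), homologous recombination (0.259), DNA replication (0.343), mitosis (0.543) and immediate-early lists (0.259) did not pass. The mitosis list did not pass without wild-type array 1 (adjusted p = 0.0834) or 2 (0.0816) or lymph node 279 (0.0616), 292 (0.0743) or 381 (0.0588). The early B-lineage list did not pass without wild-type array 1 (adjusted p = 0.0877) or lymph node 317 (0.0650).

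**Figure D3:**
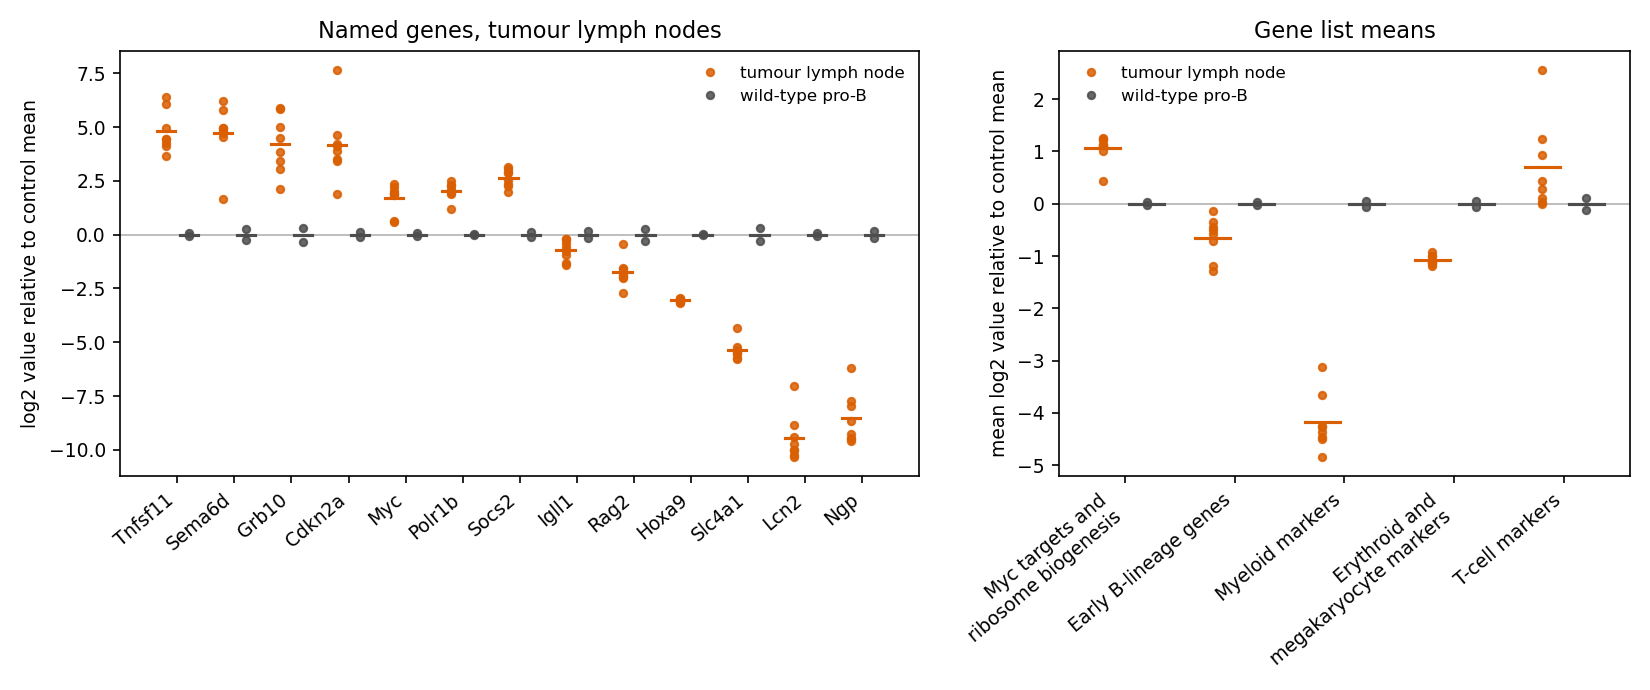
Values of named genes (left) and means of gene lists (right) in tumour lymph nodes and wild-type pro-B cells, as log2 values relative to the wild-type mean, with points for the 8 lymph nodes (each the mean of 2 arrays) or the 2 wild-type arrays and bars for group means. Lcn2 lies at -9.45 and Slc4a1 at -5.37, and T-cell markers are highest in a single lymph node.

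Lymph nodes also differed from each other. Enpep, a peptidase on pre-B cells, was 7.7 above the median lymph node on the log2 scale in lymph node 277 and 3.9 above it in 383. Igf1, a growth factor, was 6.3 and 6.1 above it in 279 and 292, and the transcription factor Prdm14 6.0, 6.2 and 4.7 above it in 317, 381 and 383. Mgst1 was -6.3 and -4.0 relative to it in 381 and 383, Ifitm1 -5.3 and -4.0 in 277 and 292, and Cd44 -4.5 and -3.0 in 277 and 327. Dntt ranged from -4.7 in 381 to 2.3 in 292, Nid1 from -2.8 in 327 to 4.8 in 277, Tmed6 from -2.5 in 279 to 3.9 in 278, and Myom2 was 7.0 higher in 277. The F test called 10852 of 18193 genes (59.6%) at n = 8 lymph nodes with 2 arrays each, 724 of them with a standard deviation between lymph nodes of at least 1. The median standard deviation was 0.190 between lymph nodes and 0.126 between the arrays of a lymph node. Of immunoglobulin segments 15 of 21 differed between lymph nodes (71.4%) and of T-cell receptor segments 9 of 11 (81.8%). Arrays numbered 2 differed from those numbered 1 of the same lymph nodes in 297 genes, by a median of 0.22 on the log2 scale, and the spread between duplicates may be smaller than that between separate preparations.

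**Figure D4:**
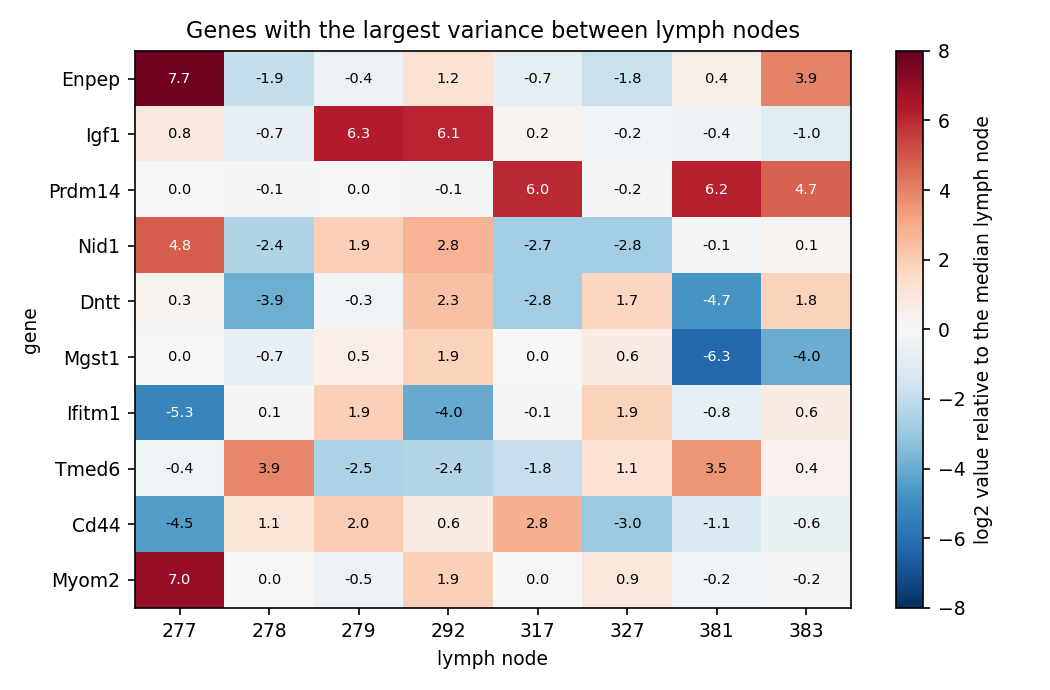
The 10 genes with the largest variance between lymph nodes: colour and number give the log2 value in each of 8 lymph nodes relative to the median lymph node. Enpep and Myom2 are highest in 277, Igf1 in 279 and 292, and Prdm14 in 317, 381 and 383.

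Genes that changed over time in the Ebf1-ER cells or with Ebf1-Engrailed were then tested in the tumours. Of the 3823 genes higher at 24 h than at 0 h, 1162 were higher and 157 lower in the tumours (adjusted p = 2.9e-14, and adjusted p = 0.22 with an estimated correlation). Independent lists would share 430 and 330. Of the 3236 genes lower at 24 h, 436 were lower and 240 higher (adjusted p = 0.020, and adjusted p = 0.36 with an estimated correlation). This call was lost without wild-type array 2 (adjusted p = 0.135), without lymph node 277 (adjusted p = 0.115) and with fry (adjusted p = 0.107). With the added lists from 24 h against 6 h, the higher genes did not pass (adjusted p = 0.58) and the lower genes were higher in the tumours (179 higher and 68 lower of 798, adjusted p = 0.0075 over the 6 added tests, and adjusted p = 0.41 with an estimated correlation). Genes lower with Ebf1-Engrailed were higher in the tumours (162 higher and 69 lower of 1031, adjusted p = 0.025, and adjusted p = 0.36 with an estimated correlation). That call was lost without Ebf1-Engrailed array 1 (adjusted p = 0.0909) or 2 (0.120), empty-vector array 1 (0.141) or 2 (0.184) or wild-type array 2 (0.0525). It was also lost with fry (0.0596), with lists of a log2 change of at least 1 (0.732) and with the variance filter (0.50), and the 100 largest changes turned direction (0.288). Genes higher with Ebf1-Engrailed did not pass (adjusted p = 0.17), but passed as lower in the tumours with fry (0.0113), with lists of at least 1 (0.0160), with the variance filter (0.0252) and with the 100 largest changes (2.6e-06). Whether either set moved in the tumours thus depends on the test and the threshold.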

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

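The tests chosen only after the results were seen were those of a 0 h state that ended by 6 h, of Ebf1 activity at 0 h, of loss of granulocyte transcripts from tumour cells, all 3 tests of the interferon genes and the count of splits.

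Immediate-early genes were higher and ribosome biogenesis genes lower at 0 h than at every later time in the Ebf1-ER cells. Lower RNA quality at 0 h is argued against only as far as the log2 ratio of 3' to 5' control probe sets can show it. That ratio differed by 0.0243 from the later arrays, where a difference under 0.5 had been set as counting against it. Centred values do not show whether the 5' probe sets lay above background, where the ratio could respond to poorer RNA. A state of the cells at 0 h that ended by 6 h, which handling before tamoxifen could bring, remains open: the mean change at 6 h was 0.959 of that at 24 h for immediate-early genes (-2.56 and -2.67) and 1.09 of it for ribosome biogenesis genes (1.89 and 1.73). Activity of Ebf1 itself stays open too, since neither list passed in the Ebf1-Engrailed cells: the ribosome biogenesis list had an adjusted p of 0.0569 (0.839 with an estimated correlation, 0.517 with fry), with 1 member higher and none lower, which neither shows nor excludes an effect. No time series without Ebf1-ER was used here, so the time in culture and Ebf1-ER cannot be told apart for these genes.

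Granulocyte transcripts were far higher in wild-type pro-B cells than in the tumours. A candidate explanation is granulocytes or their precursors in the wild-type samples. Of 18 further granulocyte genes, listed before their values were seen, 100% were higher in both wild-type arrays than in every lymph node. Chance gives 2.22% of genes, but over all 18193 genes the groups did not overlap, in either direction, for 5210. The median log2 change of the 18 genes was -5.61 (48.8-fold), with Wfdc21 at -8.02, Mmp8 at -7.64 and Hp at -7.39. The pro-B cells were sorted per the series description, and a gate on B-lineage surface markers would remove granulocytes, but the gate is not stated. Loss of these transcripts from the tumours' own B-lineage cells cannot be told apart from this by the myeloid list (median -3.71), because no wild-type pro-B cells known to be pure are among the arrays used here. The erythroid, stem and stromal lists were lower in the tumours too. A different mix of cells in the wild-type samples could therefore bear on every comparison of the tumours with them.

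Interferon response genes were higher in Ebf1-Engrailed arrays 1 and 2 and less so in array 3. As to a shift shared by both samples numbered 3, empty-vector array 3 lay 0.366 below its group's other arrays and Ebf1-Engrailed array 3 2.33 below. The ratio of 0.157 goes against an equal fall in both. However, centred values do not show whether these genes lay near background in the empty vector, where a fall could not show. A shared shift thus stays open. The difference within number 3 was smaller for most other lists too, at 0.577 to 0.717 of that within numbers 1 and 2 for 7 of the 10 other called lists, but at 1.07 for glycolysis, 1.14 for NK markers and 1.42 for myeloid markers. The ratio of 0.260 for the interferon list lay 0.318 below the lowest of the other lists, narrowly past the bound of this test. However, the interferon list was picked for its low value in number 3, which favours a low rank. The test also replaced an earlier one after the values were seen. Among 1445 other changed genes the ratio had a median of 0.643 and a lower quartile of 0.437. A weaker response of all genes thus stays open. Opposition to Ebf1 activity had been set to raise the list by a like amount in every Ebf1-Engrailed array. It did not, with differences of 2.68, 2.62 and 0.689 within numbers 1, 2 and 3. The list fell from 6 h to 24 h with an adjusted p of 0.025 by camera, but 0.254 with an estimated correlation. Neither part of that prediction was thus met in full. Opposition to Ebf1 activity stays open, as the unequal rise rests on array 3.

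Among the 10 splits of the 6 arrays of this experiment limma called 2474 genes in the real split and 0 in the highest of the others. These splits are too few for a share under 0.05.

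Of 115 values tested over the 8 lymph nodes, 15 had a sample far from the others, against 5.75 by chance at 1 in 20. That figure holds for independent values not chosen from these data. The 115 include genes picked for their variance between these lymph nodes, and list means beside their own members. The excess thus cannot be read against chance. Lymph node 292 held 6 of these, 279 held 4, 277 held 2, and 317, 327 and 381 held 1 each. The ratio of the gap to the whole range was compared with Dixon's critical value. In lymph node 292 it was 0.540 for Foxo1, 0.731 for Bach2 and 0.703 for Neil1, all high, and 0.543 for Polr1b, 0.583 for Ppat and 0.705 for the mean of the Myc target and ribosome biogenesis list, all low. In lymph node 279 it was 0.550 for Lcn2, 0.684 for Ier3, 0.613 for Slc4a1 and 0.559 for the mean of the NK and innate lymphoid list, all high. In lymph node 277 it was 0.636 for Sema6d, which was low, and 0.685 for Myom2, which was high. It was 0.608 for Pmaip1, high in 317, 0.551 for Oas3, low in 327, and 0.566 for Ssr4, high in 381.

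Effects at 24 h and at 6 h differed by the direct test for 13 of the genes that the fixed rule names always or for the largest changes at 24 h. Members of lists named at 24 h, such as Cd24a and Vpreb1, differed as well. The log2 differences were -1.16 for Myc, 1.15 for Rad51ap1, 2.85 for Igll1, 0.98 for Foxo1, 2.27 for Tubb3, -1.14 for Ccn3 and 0.71 for Bcat1. They were -0.66 for Nefh, 2.06 for P2rx3, -0.58 for Fos, -3.33 for Ccl3, -0.89 for Egr1 and -0.57 for Gbp8. Among these, Bcat1, Egr1, Fos, Gbp8 and Nefh lost their calls in a leave-one-out fit. Of the 16 lists that differed, the higher ones had median differences of 1.70 for mitosis, 0.56 for DNA replication, 0.54 for homologous recombination, 0.43 for early B-lineage genes, 0.21 for V(D)J recombination, 0.21 for the checkpoint and 0.17 for T-cell markers. The lower ones had -0.39 for IL-7 receptor signalling, -0.39 for stromal markers, -0.21 for interferon genes, -0.19 for Myc targets, -0.18 for NK markers, -0.17 for p53 targets, -0.14 for mature B-cell markers, -0.10 for myeloid markers and -0.10 for stem cell markers. Without 1 of the 6 h or 24 h arrays calls were lost for V(D)J recombination (adjusted p up to 0.0755), p53 targets (up to 0.129), interferon genes (0.0900), myeloid markers (up to 0.0758) and mature B-cell markers (0.129). In 1 fit over all groups those 5 lists, Myc targets (0.0510), T-cell (0.397), NK (0.162) and stem cell markers (0.207) lost their calls. Fry ended those of p53 targets (0.140) and stromal markers (0.0795), the variance filter those of p53 targets (0.246), interferon genes (0.128) and mature B-cell markers (0.0939), and the mean of probe sets that of p53 targets (0.0571). With an estimated correlation mitosis, DNA replication and homologous recombination passed.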

How the results depend on the processing

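The tests chosen only after the data were seen were the variance filter, the comparison without the samples numbered 3, the crossed numbers at 24 h, the fit without the 0 h arrays, the term for Xist-high samples and the gene lists from or in 24 h against 6 h. Of the values of named genes under the alternatives, 4700 kept their direction and their side of the threshold, 370 lost the call, 23 gained it and 11 changed direction. The 96 list calls were followed in the same way: 1517 values kept the call, 140 lost it and 2 changed direction. The estimated correlation ended 64 of these calls, leaving out 1 sample 23, 1 fit over all groups 21, the variance filter 14, fry 8, the mean of probe sets 6, the term for Xist-high samples 2, and the replicate block and the fit without the samples numbered 3 each 1. Lists that had not passed were followed only in the counts: with fry 14, 23, 24, 25, 21 and 6 lists passed where camera gave 11, 18, 19, 21, 16 and 11 for Ebf1-Engrailed, 6, 12 and 24 h, 24 h against 6 h and the tumours. Signal over background cannot be read from centred values, so what it limits is unknown. The level filters, quantile normalisation and trend fits of the plan were not run because centred values hold no levels.

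Requiring a log2 change of at least 1 left 1012 genes for Ebf1-Engrailed, 1798, 2286 and 2074 at 6, 12 and 24 h, 316 for 24 h against 6 h and 1274 for the tumours. At an adjusted p under 0.01 there were 1098 for Ebf1-Engrailed, 655 for 24 h against 6 h and 1799 for the tumours. These thresholds are stricter by construction. In 1 fit over all groups of the series the counts were 3399, 4345 and 4036 at 6, 12 and 24 h and 204 for 24 h against 6 h, where 7 lists passed. The cause was not tested. The Ebf1-Engrailed count was 4772 without the samples numbered 3, of which 2431 genes were shared with the 2474. With the term for Xist-high samples 1704 genes were called in the tumours, and the homologous recombination and DNA replication lists turned direction (adjusted p = 0.979 and 0.725). The same fit ended the calls of the early B-lineage list (0.413) and of excision and mismatch repair (0.192). Its tumour difference is that of the Xist-low, male lymph nodes 279 and 292 alone, so sex and these lymph nodes cannot be told apart. The cause was not tested. Leaving out 1 array or lymph node at a time gave 1134 to 3184 genes for Ebf1-Engrailed, 617 to 2017 for 24 h against 6 h and 1117 to 3985 for the tumours.

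With an estimated correlation 0 lists passed with camera for Ebf1-Engrailed, where 8 had an unadjusted p under 0.05 and 14 passed with fry. At 6, 12 and 24 h 8, 9 and 9 passed, and 3 each for 24 h against 6 h and the tumours. For genes higher and lower at 24 h tested in Ebf1-Engrailed the estimated correlation gave an adjusted p of 0.352 and 0.254, and in the tumours 0.218 and 0.360. For genes higher and lower with Ebf1-Engrailed tested at 24 h it gave 0.218 and 0.0669, and for the lower genes in the tumours 0.360. Fry gave 0.0964 for genes higher at 24 h tested in Ebf1-Engrailed and 0.107 for genes lower at 24 h tested in the tumours. Genes higher with Ebf1-Engrailed, which did not pass in the tumours (adjusted p = 0.17), passed as lower there with fry (0.0113), with lists of a log2 change of at least 1 (0.0160), with the 100 largest changes (2.6e-06) and with the variance filter (0.0252). Genes lower with Ebf1-Engrailed lost their call there with fry (0.0596), with lists of at least 1 (0.732) and with the variance filter (0.50), and turned direction with the 100 largest changes (0.288). Those 100 genes did not pass at 24 h against 0 h (0.163). With lists from 24 h against 6 h, the higher genes did not pass in the tumours (0.580) and the lower genes turned direction (0.00828). That call of the lower genes was lost with an estimated correlation (adjusted p = 0.41 over the 6 added tests), and with lists of at least 1 or of 100 genes they did not pass (0.698 and 0.668), while the higher genes passed as lower in the tumours (0.0460 and 0.0053). The cause was not tested for any of these. Over single left-out samples the adjusted p ranged from 0.00023 to 0.0644 for genes lower at 24 h in Ebf1-Engrailed, from 0.0017 to 0.135 for the same genes in the tumours and from 0.00024 to 0.184 for genes lower with Ebf1-Engrailed in the tumours.

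Values that turned direction and had not passed were Foxo1 at 12 h, -0.22 with the mean of all probe sets and between -0.0133 and 0.0240 over the left-out arrays (lowest without 0 h array 1). Aurkb at 6 h lay between -0.190 and 0.0431 (highest without 0 h array 2). Pax5 at 24 h against 6 h was 0.0185 with the mean of all probe sets and between -0.105 and 0.0940 over the left-out arrays, with positive values without 6 h array 2 and 24 h array 2. Pax5 in the tumours was -0.18 with that mean. Rad51ap1 in the tumours lay between -0.147 without wild-type array 2 and 0.0713 without lymph node 292, was positive without wild-type array 1 and lymph node 279 too, and was 0.0318 with array quality weights. The cause was not tested.

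With the replicate number as a block 3497 genes were called for Ebf1-Engrailed, 2422 of them shared with the 2474, and the NK and innate lymphoid list did not pass (adjusted p = 0.0503). The block counts were 6121, 6964, 6791 and 1299 at 6, 12 and 24 h against 0 h and for 24 h against 6 h. There the arrays share only a number: correlations of same-numbered deviations were 0.104, 0.0900, -0.145, -0.171, 0.134 and -0.162 over pairs of times. With the 24 h numbers crossed the counts were 6428, 7350, 7140 and 1637.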

Other observations

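The tests of chromosomes were written before their values were seen, except that chromosome 15 was singled out after the deviations of all chromosomes had been seen.

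Cdkn2a, a tumour suppressor that arrests the cell cycle, lay 7.65 above wild-type cells on the log2 scale in lymph node 279 and 1.87 in lymph node 381. Relative to the median lymph node Myc stood at -1.33 in 317, -1.30 in 292 and 0.11 in 279. Xist-high samples, female by their lack of Y-linked transcripts, numbered 6 of 8 lymph nodes and 0 of 2 wild-type arrays.

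Whole-chromosome gains or losses were tested as a source of differences between lymph nodes. Over 19 autosomes and 17516 genes placed on them, none of 152 pairs of lymph node and chromosome passed the bound of 0.15 on both arrays that was set in advance, and the bound was not moved. The largest absolute median deviation was 0.137, for chromosome 15 in lymph node 279, and it lay closer to the bound than its own spread between arrays, so the test leaves such changes open; that reading of a near miss was chosen after the value was seen. The median over all pairs was 0.00861.

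Chromosome 15 genes lay 0.137 above the other lymph nodes in 279 and 0.128 above them in 317, and the largest deviation among the 150 other pairs was 0.0497. In 10000 random lists of 729 genes the largest deviations were 0.0418 and 0.0391. A gain of the whole chromosome may raise both its first and its second part by gene order: these stood at 0.140 and 0.0978 in 279 and at 0.116 and 0.104 in 317. The lowest, 0.0978, missed the bound of 0.1 set before the parts were computed, so a gain is neither shown nor excluded. Myc lies on chromosome 15.

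The 18 hybridisation spike-in probe sets had a median of -6.26 on 24 h array 2 of the Ebf1-ER cells, with a lowest value of -10.7. On the other 7 arrays of that experiment they lay between -0.284 and 0.874.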
